A study of Mus musculus with 12 samples.

How the data were processed

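Liver RNA of 12 mice, in 4 groups of 3 per the labels (flox or cre genotype, control or MCD diet), was studied from the deposited processed tables alone, and no reads were mapped again. The labels give poly(A) RNA, a SMARTER library kit, C57BL/6 mice labelled male and aged 6 to 8 weeks, and the mm10 genome. Per the labels the authors trimmed reads with cutadapt, checked them with FastQC, aligned them with HISAT2 and quantified them with StringTie, with edgeR for later steps. The notes give no versions. The deposited count tables hold estimated counts made by the authors for 55401 genes and 142604 transcripts. The values show that these are not counts of reads taken 1 by 1. For 92.9% to 95.4% of the transcripts of a library the estimated count equals the next whole number above FPKM times length times a constant per library, and each gene's count is the sum of its transcripts' counts. The deposited expression tables hold FPKM values, normalised by the authors to length and library size, on a linear scale. Their headers name no unit, which was read from this relation to the counts. Reduced versions of the expression tables and tables of correlations between libraries were not used, since the full tables hold the values. The libraries totalled 40883986 to 65516723 estimated counts, and 3 counts over a group, the floor used for genes at 0, were 0.0144 to 0.0258 CPM. Of the gene identifiers 99.5% were found in GENCODE vM21, 99.4% of those with the same start and end and 96.7% with the same symbol. On more than 1 row stood 107 symbols, and rows were kept apart by identifier, save where Pakap or Nnt rows are given as summed.

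Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, libraries were scaled with TMM, and quasi-likelihood F tests (glmQLFit, glmQLFTest, 2-sided) were run on 1 fit of all 12 libraries with a mean per group. The 5 comparisons were MCD against control diet in flox and in cre mice, cre against flox on MCD and on the control diet, and the difference of the diet effects (interaction). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 16523 tested genes were called. Levels are TMM-normalised CPM. An SE is the size of the log2 fold change divided by the square root of its F value, not a separate estimate. Because 3 against 3 libraries allow no exact permutation p below 0.1 for a single gene, adjusted p-values of the fit across all genes are given, and the 1 test of a single value, Lpcat3 over 6 against 6 libraries, is an exact permutation test on log2(CPM + 1). Overlaps between comparisons were set against the product of the counts over the number of genes.

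The 34 gene lists were fatty acid oxidation, PPARalpha targets, fatty acid synthesis and desaturation, cholesterol synthesis, triglyceride synthesis and lipid droplets, lipoprotein assembly, phospholipid synthesis and remodelling, methionine and one-carbon metabolism, bile acids, sulfotransferases, xenobiotic cytochromes P450, male-biased and female-biased liver genes, extracellular matrix, stellate cells, resident macrophages, recruited and lipid-associated macrophages, lymphocytes (T, NK and B), neutrophils, endothelium, cholangiocytes, hepatocytes, chemokines and cytokines, interferon response, acute phase, unfolded protein response, NRF2 and glutathione, glycolysis and gluconeogenesis, proliferation, circadian clock, immediate-early genes, pancreas and red cells, adipocytes and gallbladder, and mitochondrially encoded genes. Some genes stand in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, with p adjusted over the 34 lists of a comparison, and members were counted over all genes and adjusted over the list alone. Comparisons, tests, lists, the alternatives of the next paragraph save those named there as later, and the rule for named genes were fixed before the data were examined. The rule named Lpcat3 and Sult1e1 throughout. It added the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean of at least 5 CPM, no overlap between the 3 and 3 libraries (not asked of the interaction) and an established symbol. It added up to 4 called members of each list with the smallest p, or up to 2 as values where none passed, and the 5 genes with the smallest p where fewer than 5 genes resulted. The text gives a part of these genes. Maff, Cyp8b1 and Tfpi2 lie outside the rule.

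Each result was recomputed under alternatives. Most change 1 choice, but DESeq2 brings its own size factors and test, and the FPKM fits change values, scaling, filter and test together. For scaling and filters these were DESeq2's size factors, no filter, and a CPM of at least 1 in at least 3 libraries. For the test they were DESeq2 1.42.0, limma voom 3.58.1, the replicate number as a block, only the 6 libraries compared, and a log2 fold change of at least 1 as a second condition. The FPKM values were tested with limma as log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1, and as log2(FPKM + 1) without that filter. Each library was left out in turn, and the lists were tested with camera at an estimated correlation and with fry. Chosen after the data were seen were a fit without the library labelled cre MCD 3 and flox control 3, a fit without ribosomal RNA rows, and the log2 ribosomal share as a covariate. The fit was tested on simulated data in which 100 genes per comparison were changed 2-fold and another 100 were changed 4-fold. In the order of comparisons above it called 9%, 8%, 12%, 11% and 2% of 2-fold and 52%, 61%, 57%, 60% and 37% of 4-fold changes, with 1 to 6 false calls. Each list method called the 1 list that had been shifted, and fry also called 1 list that had not. Genes were simulated independently of each other, so this cannot show how the methods behave when members of a list are correlated.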

Results

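RNA was sequenced from 12 mouse livers in 4 groups of 3. The mice carried loxP-flanked Lpcat3 alleles without cre (flox) or with cre (cre), and each genotype ate either a control diet or a methionine- and choline-deficient (MCD) diet. The MCD diet, given for 8 weeks to bring on steatohepatitis, limits phosphatidylcholine synthesis and lipoprotein export in hepatocytes, and all mice fasted for 12 h before collection. Lpcat3 encodes lysophosphatidylcholine acyltransferase 3, which places polyunsaturated acyl chains into phospholipids, and the series asks what it does in fatty liver. The title of the series also names a gene that was read here as Sult1e1, the estrogen sulfotransferase. The libraries held 40883986 to 65516723 estimated counts and 17631 to 19988 genes above 0. The row of 1 ribosomal RNA gene (CT010467.1, chromosome 17, 39846353 to 39848201) took 5.6% to 43% of a library's counts, with the highest share in flox control 1 and the lowest in the library labelled cre MCD 3 (5.6%) and flox control 3 (7.34%). The same 2 libraries had the lowest shares of mitochondrial ribosomal RNA (1.82% and 1.92%) and the highest correlation of deviations from their group means between groups (r = 0.345). Coding genes of the mitochondrial genome took 6.26% to 30%, with group means of 10.3% ± 4.24 in flox control, 23.4% ± 7.74 in cre control, 11.5% ± 1.63 in flox MCD and 9.03% ± 1.77 in cre MCD (SD, n = 3). No 95% Wilson interval of these shares was wider than 0.014 percentage points to either side. Such intervals, like the bounds given for genes at 0, treat the estimated counts as reads, which they are not. At best they cover counting error only. On the first principal component (29.3% of the variance) the control libraries lay at -78.7 to -3.04 and the MCD libraries at 14.8 to 78.3. Flox control 3 lay apart on the second component (13.7%), at -94 against -41.2 to 43.4 for the other 11 libraries.

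Lpcat3 (ENSMUSG00000004270, chromosome 6, 124663027 to 124704418 in GRCm38) separated the genotypes in 11 of the 12 libraries. Its level was 41.4 to 63.4 normalised CPM in the 6 flox libraries and 16.1 to 23.3 CPM in 5 of the 6 cre libraries. The remaining cre library, here called the library labelled cre MCD 3, held 56.1 CPM. Group means were 52.2 ± 9.73 CPM in flox control, 21.3 ± 1.87 in cre control, 51.1 ± 8.44 in flox MCD and 31.7 ± 21.4 in cre MCD (SD, n = 3). Over both diets the flox and cre libraries differed in a 2-sided exact permutation test (10 of 924 splits as far apart, p = 0.0108). The full-length coding transcript (ENSMUST00000004381) was at 9.9 to 24.1 FPKM in the flox libraries and listed at 0 in the same 5 cre libraries. It stood at 23.2 FPKM in the library labelled cre MCD 3. A transcript with a retained intron (ENSMUST00000135516) was at 3.54 to 5.39 FPKM in those 5 cre libraries and at 0 to 0.265 in flox. It was listed at 0 in the library labelled cre MCD 3. In the fit across all genes Lpcat3 did not pass in any comparison. The log2 fold change for cre against flox was -1.29 on the control diet (adjusted p = 0.57) and -0.69 on MCD (adjusted p = 0.66). For the diet it was -0.03 in flox mice (adjusted p = 0.98) and 0.57 in cre mice (adjusted p = 0.34), and the diet effects differed by 0.60 (adjusted p = 0.73). Without the library labelled cre MCD 3 the values became -1.40 for cre against flox on MCD (adjusted p = 0.0701), -0.131 for the diet in cre mice and -0.106 for the difference of the diet effects. Cre against flox on the control diet stayed at -1.29, but its adjusted p became 0.079 (0.317 to 0.906 without any other library). That library is not in this comparison, but all 12 libraries share the spread estimated in the fit. Without flox control 3 or flox MCD 2 the diet effect in flox mice turned to 0.141 or 0.106. Without both the library labelled cre MCD 3 and flox control 3, an alternative chosen after the data were seen, Lpcat3 passed on MCD (-1.40, adjusted p = 0.0322, against 0.0701 to 1 in all other alternatives).

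**Figure D1:**
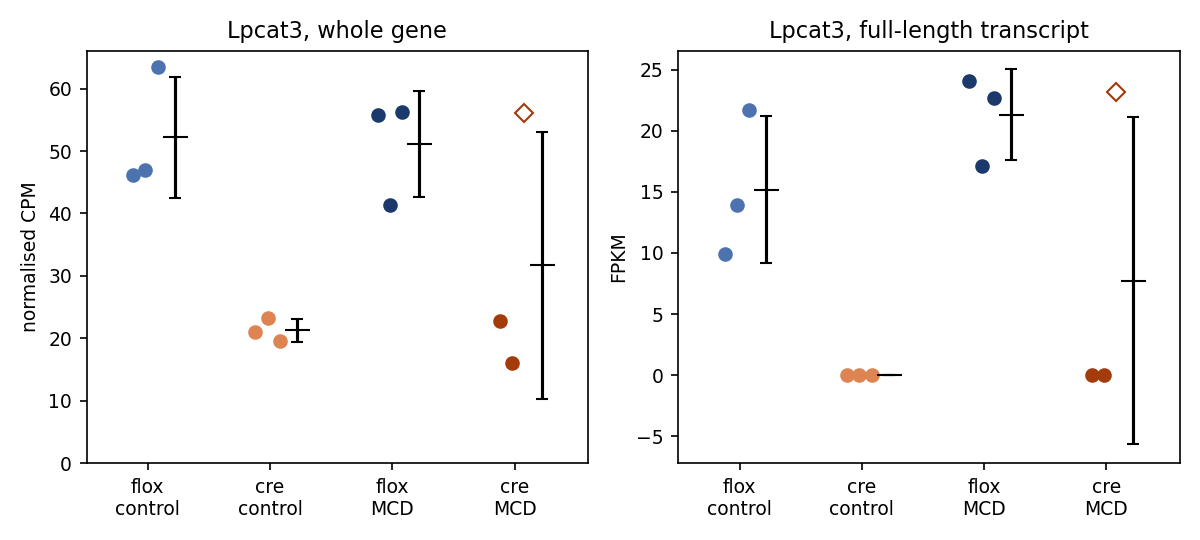
Lpcat3 in each library by group, as the whole gene in normalised CPM and as the full-length transcript in FPKM; bars are means with the SD of 3 libraries, and the open diamond is the library labelled cre MCD 3. The other 5 cre libraries lie at 16.1 to 23.3 CPM and at 0 FPKM, and the diamond lies at 56.1 CPM and 23.2 FPKM, among the flox libraries.

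Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), which inactivates estrogens by sulfation, rose on the MCD diet in both genotypes. It went from 2.95 ± 3.67 to 53.9 ± 15 CPM in flox mice (log2 fold change 4.17, SE 1.05, adjusted p = 0.034; SD, n = 3). In cre mice it went from 0.59 ± 0.512 to 14.8 ± 16.5 CPM (4.65, SE 1.13, adjusted p = 0.029). The cre MCD libraries spread from 2.71 CPM to 7.99 and, in the library labelled cre MCD 3, 33.6 CPM, while the flox MCD libraries held 44.7 to 71.3 CPM. The difference between genotypes did not pass on MCD (log2 fold change -1.86, adjusted p = 0.65) or on the control diet (-2.34, adjusted p = 0.69), and the diet effects did not differ by test (0.48, adjusted p = 0.94). The value on MCD became -3.33 without the library labelled cre MCD 3 (adjusted p = 0.291; -1.37 to -1.98 without any other), and that on the control diet became -0.493 without flox control 3 (adjusted p = 0.984; -1.75 to -2.84 without any other). The difference of the diet effects turned negative without flox control 3 (-1.37), cre control 3 (-0.103) or the library labelled cre MCD 3 (-0.987). The call in flox mice was lost without flox control 1 (3.75), flox control 2 (3.73), flox MCD 1 (3.93), flox MCD 2 (4.30) or flox MCD 3 (4.28), with adjusted p of up to 0.116. The call in cre mice was lost without cre control 1, 2 or 3, cre MCD 2 or the library labelled cre MCD 3, over a range of 3.19 to 5.16 and with adjusted p of up to 0.106.

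In all that follows, levels are normalised CPM as mean ± SD with n = 3 libraries, and fold changes are log2 values from edgeR with p adjusted over 16523 genes. Such p-values measure the spread between these samples. A gene named as risen or fallen kept that call in each of the 12 fits that left out 1 library unless its paragraph says otherwise. Members of a list are counted over all genes tested and, where this differs, adjusted over the list alone. With 1 library left out, 55 of the 66 counts of 1 to 4 members moved over 1.5 times in at least 1 fit, so these small counts are not firm, and each move of a larger count over all genes is given in its paragraph. Lists were tested as sets with camera at a preset correlation, and the p with a correlation estimated from the data follows each call. With that p only the female-biased list for the diet in flox mice and the immediate-early list for genotype on MCD held their calls.

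The first comparison asks what the MCD diet changed in livers of flox mice. As sets, recruited macrophage, matrix, and NRF2 and glutathione genes rose, and xenobiotic cytochromes P450, bile acid genes and sulfotransferases fell. All 6 calls were lost with the other test (adjusted p = 0.091 to 0.28 with an estimated correlation). Cd63 (chromosome 10, 128900989 to 128912822), an endosomal tetraspanin among the markers of lipid-associated macrophages, went from 5.99 ± 0.588 to 58.1 ± 11.6 CPM (log2 fold change 3.28, SE 0.24, adjusted p = 7.8e-06). Cyp2c54 (chromosome 19, 40037940 to 40073827), a xenobiotic cytochrome P450, fell from 273 ± 133 to 2.5 ± 0.464 CPM (-6.77, SE 0.48, adjusted p = 7.3e-06). In all, 871 of 16523 genes passed, 437 higher and 434 lower, of which 379 and 322 changed at least 2-fold.

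Recruited macrophage, matrix and stellate cell markers were among the genes that rose. Of the 22 markers of recruited and lipid-associated macrophages 9 rose and 0 fell (18 and 0 adjusted over the list alone). The list rose as a set (adjusted p = 3.7e-17, and adjusted p = 0.091 with an estimated correlation). Mmp12, the macrophage elastase, went from 0.15 ± 0.136 to 34.0 ± 19.5 CPM, and Lgals3, galectin 3, from 5.74 ± 1.6 to 71.5 ± 37.8 CPM. Gpnmb, a glycoprotein of lipid-laden macrophages, had 3 counts in the flox control group and 30.0 ± 17.9 CPM on MCD, a ratio of 1220. A binomial 95% interval of 416 to 5910 treats these counts as reads. Since they are estimates rounded up, the error of this ratio is not known. Among 34 extracellular matrix genes 8 rose and 0 fell (21 and 1 over the list alone), Col4a1, a basement membrane collagen, from 11.4 ± 2.49 to 29.5 ± 8.56 CPM. The matrix set rose (adjusted p = 1.8e-10, and adjusted p = 0.17 with an estimated correlation). Among 22 stellate cell markers 3 rose (13 over the list alone), including the proteoglycan Dcn (log2 fold change 1.16) and the globin Cygb (1.73). Stellate markers rose as a set (adjusted p = 1.9e-05, and adjusted p = 0.091 with an estimated correlation). Neutrophil markers rose as a set (adjusted p = 0.0017, and adjusted p = 0.15 with an estimated correlation), with 1 of 7 risen and 4 over the list alone. Cholangiocyte markers did so too (adjusted p = 0.0049, and adjusted p = 0.19 with an estimated correlation), with 1 of 16 risen and 5 over the list alone. Of 23 chemokines and cytokines 1 rose, the TWEAK receptor Tnfrsf12a (1.98), and 2 fell (7 and 3 over the list alone). As a set they rose (adjusted p = 0.0049, and adjusted p = 0.27 with an estimated correlation). Resident macrophage markers did not change as a set (adjusted p = 0.4), with 2 of 16 risen and 1 fallen (3 and 3 over the list alone). Of 25 lymphocyte (adjusted p = 0.67) and 20 endothelial markers (adjusted p = 0.65) 0 passed. Hepatocyte markers fell as a set (adjusted p = 1.3e-07, and adjusted p = 0.28 with an estimated correlation), with 7 of 24 fallen and 8 over the list alone. Otc of the urea cycle went from 396 ± 106 to 144 ± 29.2 CPM. The 8 matrix genes became 4, 2 and 3 without flox control 1, 2 and 3, and 2 without flox MCD 1 or flox MCD 3. The 7 hepatocyte genes became 4 without flox control 3, 2 without flox MCD 1 and 1 without flox MCD 2 or flox MCD 3.

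Lipid genes moved in both directions. Of 26 PPARalpha targets 7 rose and 1 fell (10 and 2 over the list alone), and the set rose (adjusted p = 3.6e-07, and adjusted p = 0.27 with an estimated correlation). Cyp4a31, of the fatty acid omega-hydroxylases, went from 7.86 ± 0.982 to 104 ± 11.5 CPM (log2 fold change 3.73, SE 0.21, adjusted p = 5.3e-07). The fatty acid transporter Cd36 went from 89.6 ± 33 to 316 ± 30.8 CPM and the hormone Fgf21 from 4.69 ± 2.77 to 41.4 ± 2.74 CPM. Fatty acid oxidation did not change as a set (adjusted p = 0.094), and the acyl-CoA thioesterase Acot2 (2.29) was the 1 member of 34 that rose. Of 27 genes of triglyceride synthesis and lipid droplets 4 rose and 1 fell (6 and 1 over the list alone). This set rose (adjusted p = 0.00021, and adjusted p = 0.31 with an estimated correlation), the droplet protein Cidec from 0.553 ± 0.372 to 40.1 ± 22.3 CPM, while the phosphatidate phosphatase Lpin1 fell (-2.22). Of 28 genes of fatty acid synthesis and desaturation 3 rose and 6 fell (3 and 9 over the list alone), with the elongase Elovl6 at -1.65 and ATP citrate lyase, Acly, at -1.49. The set fell (adjusted p = 0.0068, and adjusted p = 0.2 with an estimated correlation), a call lost without flox control 3 (adjusted p = 0.077), and its 6 fallen genes became 3 without flox MCD 1 and 2 without flox MCD 2. The desaturase Scd1 went from 2370 ± 87.7 to 94.5 ± 67.5 CPM, a call lost without flox MCD 1 or flox MCD 2 (adjusted p of up to 0.0611). Of 25 cholesterol synthesis genes 0 rose and 3 fell (0 and 6 over the list alone), including the sterol reductase Tm7sf2 (-2.28). Cholesterol synthesis fell as a set (adjusted p = 1.4e-05, and adjusted p = 0.33 with an estimated correlation). The secreted apolipoprotein Apoa4 (chromosome 9, 46240696 to 46243459) went from 151 ± 93 to 3220 ± 517 CPM. Its lipoprotein list did not change as a set (adjusted p = 0.07), with 2 of 22 risen and 3 fallen (3 and 6 over the list alone). None of 30 genes of phospholipid synthesis and remodelling, the list that holds Lpcat3, passed (adjusted p = 0.26). Of 31 genes of methionine and one-carbon metabolism 1 rose, Mthfd1l of mitochondrial folate metabolism (2.57), and 2 fell (3 and 7 over the list alone), among them sarcosine dehydrogenase, Sardh (-1.37). This list did not change as a set (adjusted p = 0.12).

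Lists of detoxification and sex-biased genes held more falls than rises. Of 24 xenobiotic cytochromes P450 0 rose and 8 fell (1 and 12 over the list alone). They fell as a set (adjusted p = 1e-09, and adjusted p = 0.091 with an estimated correlation). Of 16 sulfotransferases 1 rose and 5 fell (1 and 8 over the list alone), Sult2a8 from 429 ± 180 to 26.0 ± 3.22 CPM. Sulfotransferases fell as a set (adjusted p = 1.9e-06, and adjusted p = 0.098 with an estimated correlation). Of 27 genes of bile acid synthesis and transport 2 rose and 5 fell (2 and 10 over the list alone), including Slc27a5, the bile acid CoA ligase (-1.65), and the uptake transporter Slco1a1 (-3.72). The bile acid set fell (adjusted p = 1.8e-05, and adjusted p = 0.091 with an estimated correlation). The 5 fallen sulfotransferases became 3 without flox MCD 1, and the 5 fallen bile acid genes 3 without flox MCD 2 or flox MCD 3. Of 29 female-biased liver genes 1 rose and 12 fell (3 and 15 over the list alone), Cyp3a16 from 71.9 ± 41.8 to 0.283 ± 0.116 CPM. Female-biased genes fell as a set (adjusted p = 6.8e-11, and adjusted p = 0.044 with an estimated correlation). Of 26 male-biased genes 4 rose and 7 fell (5 and 10 over the list alone), such as the carboxylesterase Ces2a (-2.26) and the major urinary protein Mup7 (-4.68). They too fell as a set (adjusted p = 5.4e-05, and adjusted p = 0.26 with an estimated correlation). Beside these lists stands the measured fact that all 12 libraries, labelled male, held Xist (chromosome X, 103460366 to 103483254) at 116 to 685 CPM. None held a count of the Y-linked genes Ddx3y, Uty, Eif2s3y or Kdm5d. The Mup, Sult2a, Gsta, Cyp2c and Cyp3a genes belong to families of similar copies, so their counts per copy are uncertain.

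Stress genes moved by list. Of 38 NRF2 and glutathione genes 12 rose and 1 fell (18 and 4 over the list alone), among the risen heme oxygenase Hmox1 (2.06) and Gstp1 (1.69), with sulfiredoxin, Srxn1, from 25.4 ± 5.34 to 72.3 ± 10.7 CPM. The set rose (adjusted p = 4.2e-05, and adjusted p = 0.28 with an estimated correlation), and its 12 risen genes became 6 without flox control 2 or flox MCD 1 and 5 without flox MCD 3. Of 24 immediate-early genes, transcribed within minutes of a stimulus, 10 rose and 1 fell (16 and 1 over the list alone). Atf3 went from 2.41 ± 0.707 to 16.5 ± 6.69 CPM and Klf6 from 10 ± 0.259 to 30.1 ± 9.24 CPM. Immediate-early genes rose as a set (adjusted p = 3.1e-10, and adjusted p = 0.081 with an estimated correlation). Of 32 interferon response genes 0 rose and 5 fell (1 and 11 over the list alone), with the GTPases Iigp1 at -1.13 and Igtp at -1.30. Interferon genes fell as a set (adjusted p = 4.2e-05, and adjusted p = 0.27 with an estimated correlation). Their 5 falls became 3 without flox control 1 or flox MCD 2, 8 without flox control 3 and 2 without flox MCD 1. Proliferation genes rose as a set (adjusted p = 0.045, and adjusted p = 0.61 with an estimated correlation), with 1 of 30 risen and 3 over the list alone. That call was lost without flox control 2, flox control 3, flox MCD 3 or cre MCD 2 (adjusted p of 0.051 to 0.44). The unfolded protein response did not change as a set (adjusted p = 0.23), with 3 of 29 risen and 2 fallen (4 and 3 over the list alone), and its median of -0.38 and mean of 0.21 differed in sign. Its member Asns, asparagine synthetase, had no count in flox control and was at least 232-fold higher on MCD, against 3 counts over the group. The acute phase list did not change (adjusted p = 0.39, median -0.23, mean 0.00373), with 3 of 25 risen and 2 fallen (5 and 5 over the list alone). It held the pentraxin Apcs at 2.00 and the orosomucoid Orm3 at -2.54. Glycolysis and gluconeogenesis did not change (adjusted p = 0.17), with 3 of 34 risen and 2 fallen (3 and 3 over the list alone), aldolase Aldoa at 1.30 and glycogen phosphorylase Pygl at -1.25. None of 21 circadian (adjusted p = 0.12), 8 pancreas and red cell (adjusted p = 0.92, median 0.00528 with a test direction of lower) and 15 mitochondrially encoded genes (adjusted p = 0.39) passed. Of 7 adipocyte and gallbladder genes 1 rose and 1 fell (adjusted p = 0.21).

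With 1 library left out, the 871 calls became 543 without flox control 2, 438 without flox MCD 1, 521 without flox MCD 2 and 425 without flox MCD 3 (range 425 to 1055), and DESeq2 called 1653, of which 868 were shared. On the deposited FPKM values, which were not TMM-scaled, the median of all genes moved by 0.415. The calls there, 1685 higher and 130 lower, include that shift. The TMM factors of the main fit were 0.684 to 0.993 in flox control and 1.18 to 1.25 in flox MCD. The FPKM medians of fatty acid synthesis (0.335), cholesterol synthesis (0.0938) and bile acid genes (0.103) turned positive, although none of them did so relative to the median of all genes.

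**Figure D2:**
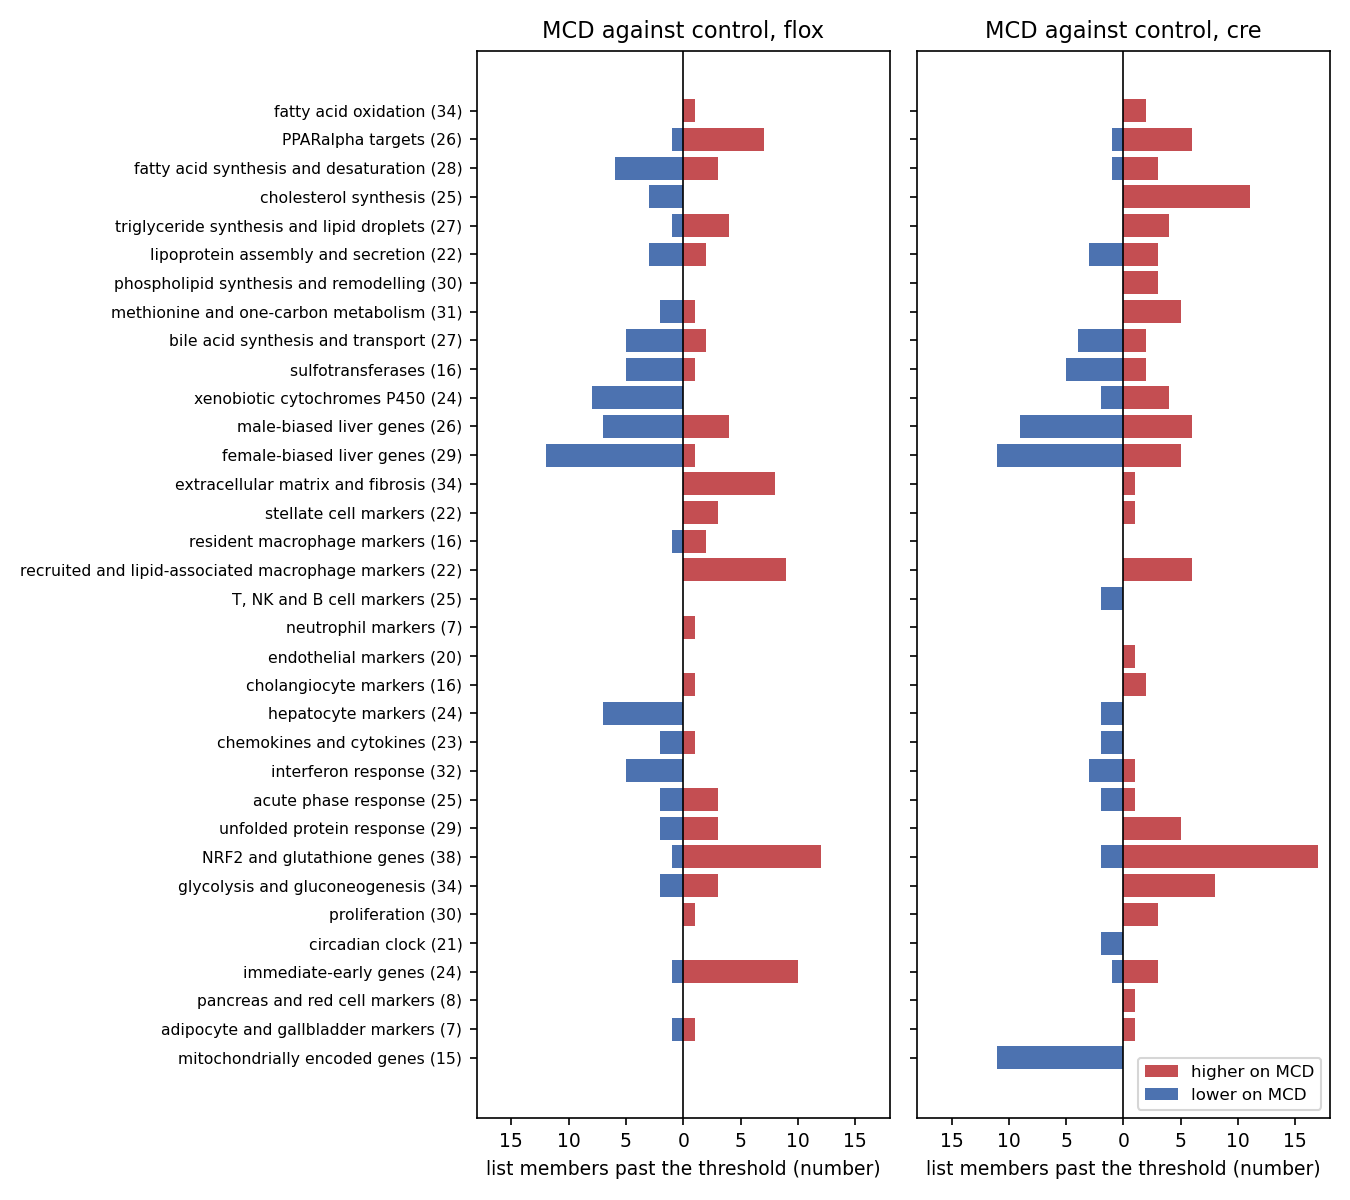
Number of genes per list past an adjusted p of 0.05 for the MCD diet against the control diet, in flox and in cre mice; red bars count higher and blue bars lower genes, and the number tested stands in brackets. In flox mice recruited macrophage, matrix and immediate-early lists hold mainly higher genes. In cre mice 11 cholesterol synthesis genes are higher (1 to 15 with 1 library left out) and 11 mitochondrially encoded genes are lower (1 to 12).

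The second comparison asks what the same diet changed in cre mice, with the library labelled cre MCD 3 among the 3 on MCD. Cd63 rose again, from 5.06 ± 1.36 to 80.9 ± 8.94 CPM (SE of the log2 fold change 0.25, adjusted p = 4.7e-06), and Cyp2c54 fell from 500 ± 200 to 11.8 ± 3.93 CPM (-5.40). Of 25 cholesterol synthesis genes 11 rose, among them Fdps, farnesyl diphosphate synthase (chromosome 3, 89093588 to 89101959), from 26.7 ± 14.6 to 143 ± 48 CPM (2.42, SE 0.36, adjusted p = 0.0019). Of 15 mitochondrially encoded genes 11 fell, and without cre MCD 2 each of these 2 counts was 1. In all, 1118 genes passed, 616 higher and 502 lower, 482 and 385 of them at least 2-fold. Between the genotypes 195 genes were called higher in both (16.3 by chance), 191 lower in both (13.2 by chance) and 0 in opposite directions. Of the genes called in flox mice 93.9% had the same sign in cre mice, and across all genes, which are not independent replicates, the log2 fold changes of the diet correlated with Pearson's r of 0.467.

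All lipid lists but the lipoprotein list held more rises than falls in cre mice. Of 25 cholesterol synthesis genes 11 rose and 0 fell (19 and 0 over the list alone). The set rose (adjusted p = 2.4e-12, and adjusted p = 0.35 with an estimated correlation), and the 11 genes became 5 without cre control 1, 4 without cre control 2 and 1 without cre MCD 2. Pmvk (1.72) and Lss (1.62), enzymes of the pathway, lost their calls without cre MCD 2 (adjusted p of 0.0579 and 0.0801). Of 26 PPARalpha targets 6 rose and 1 fell (10 and 1 over the list alone), with Cyp4a31 at 3.04 and Pdk4, which restrains glucose oxidation, going from 11.3 ± 2.64 to 65.1 ± 39.3 CPM. PPARalpha targets rose as a set (adjusted p = 2.4e-05, and adjusted p = 0.46 with an estimated correlation), and the 6 became 3 without cre control 2 or the library labelled cre MCD 3. Of 27 triglyceride and lipid droplet genes 4 rose (9 over the list alone), Cidec from 0.525 ± 0.125 to 11.6 ± 2.99 CPM. They rose as a set (adjusted p = 0.00019, and adjusted p = 0.45 with an estimated correlation). Fatty acid oxidation rose as a set (adjusted p = 0.014, and adjusted p = 0.7 with an estimated correlation), with 2 of 34 members risen. That call was lost without cre control 1 or the library labelled cre MCD 3 (adjusted p of 0.06 to 0.45). Of 28 fatty acid synthesis genes 3 rose and 1 fell (8 and 3 over the list alone), the ligase Acsl4 (1.87) and the elongase Elovl7 (3.99) among the risen. Fatty acid synthesis rose as a set (adjusted p = 0.017, and adjusted p = 0.35 with an estimated correlation), a call lost without cre control 2 or the library labelled cre MCD 3 (adjusted p of 0.067 to 0.12). Of 30 phospholipid genes 3 rose (5 up and 2 down over the list alone, set adjusted p = 0.11). Among them Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine, went from 110 ± 16.2 to 275 ± 33.9 CPM. Of 31 methionine and one-carbon genes 5 rose (6 up and 1 down over the list alone, set adjusted p = 0.17). Mat2a, which makes S-adenosylmethionine, went from 23.8 ± 2.91 to 98.0 ± 19.7 CPM. The 5 became 3 without cre control 1, cre control 3, flox MCD 3 or cre MCD 2 and 2 without cre control 2. The lipoprotein list did not change (adjusted p = 0.58, median -0.14, mean 0.09), with 3 of 22 risen and 3 fallen (3 and 4 over the list alone). It held Apoa4 at 3.34 and the phospholipid transfer protein Pltp at -3.21.

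Of the 15 mitochondrially encoded genes 11 fell (12 over the list alone), mt-Atp8 of the ATP synthase from 578 ± 304 to 82.7 ± 29.3 CPM. They fell as a set (adjusted p = 4.3e-12, and adjusted p = 0.35 with an estimated correlation). The 11 became 4 without cre control 1, 2 without cre control 2, 7 without flox MCD 3, 1 without cre MCD 2 and 4 without the library labelled cre MCD 3. Beside this, the share of all counts in mitochondrial coding genes was 23.4% ± 7.74 in cre control and 9.03% ± 1.77 in cre MCD. Of 38 NRF2 and glutathione genes 17 rose and 2 fell (22 and 3 over the list alone), with Gstm3 at 3.19 and Gstp1 at 2.04, while the metallothionein Mt1 fell from 450 ± 27.3 to 56.1 ± 15 CPM. The NRF2 set rose (adjusted p = 7.4e-11, and adjusted p = 0.35 with an estimated correlation). Glycolysis and gluconeogenesis rose as a set (adjusted p = 0.00059, and adjusted p = 0.35 with an estimated correlation), with 8 of 34 risen (12 up and 1 down over the list alone). The 8 became 5, 2 and 3 without cre control 1, 2 and 3, 3 without cre MCD 2 and 4 without the library labelled cre MCD 3. The unfolded protein response rose as a set (adjusted p = 0.018, and adjusted p = 0.63 with an estimated correlation), with 5 of 29 risen (6 up and 1 down over the list alone). Without cre MCD 2 its call was lost (adjusted p = 0.16), and the 5 became 2 without cre control 1, cre control 2 or cre MCD 2 and 3 without cre control 3. Of 30 proliferation genes 3 rose, among them cyclin D1, Ccnd1, from 24.1 ± 8.57 to 132 ± 23.4 CPM. The proliferation set rose (adjusted p = 0.046, and adjusted p = 0.63 with an estimated correlation). That call was lost without flox control 1 or 3, cre control 2 or 3, flox MCD 1 or the library labelled cre MCD 3 (adjusted p of 0.05 to 0.6).

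Of 22 recruited and lipid-associated macrophage markers 6 rose in cre mice (9 over the list alone), and so did the set (adjusted p = 1.5e-07, and adjusted p = 0.35 with an estimated correlation). The 6 became 3, 2 and 3 without cre control 1, 2 and 3, 3 without cre MCD 2 and 2 without the library labelled cre MCD 3. Mmp12 was among them (6.84, and 10.8 without cre control 1). Gpnmb (4.12) lost its call without cre control 2, cre control 3 or the library labelled cre MCD 3 (adjusted p of up to 0.0705). Extracellular matrix genes rose as a set (adjusted p = 0.0014, and adjusted p = 0.47 with an estimated correlation), with 1 of 34 risen. Stellate cell genes did so too (adjusted p = 0.0076, and adjusted p = 0.35 with an estimated correlation), with 1 of 22 risen. Cholangiocyte markers rose (adjusted p = 0.014, and adjusted p = 0.35 with an estimated correlation), with 2 of 16 risen, a set call lost without cre control 2 (adjusted p = 0.067). Of 32 interferon genes 1 rose and 3 fell (1 and 6 over the list alone), with Gbp3 at -1.83. Interferon genes fell as a set (adjusted p = 0.0069, and adjusted p = 0.47 with an estimated correlation), a call lost without cre MCD 1 (adjusted p = 0.097). Of 29 female-biased genes 5 rose and 11 fell (7 and 12 over the list alone), and the set fell (adjusted p = 0.0039, and adjusted p = 0.35 with an estimated correlation). Its median of -0.04 became 0.232 on FPKM values, and -0.0444 once the shift of all genes was taken off. The 5 rises became 2 without cre control 1 or 2, and 3 without flox MCD 1, flox MCD 3, cre MCD 2 or the library labelled cre MCD 3, and the 11 falls became 7 without cre MCD 2. Of 26 male-biased genes 6 rose and 9 fell (10 and 10 over the list alone), and the set fell (adjusted p = 0.046, and adjusted p = 0.6 with an estimated correlation). Leaving out any of 9 libraries ended that call (adjusted p of 0.052 to 0.32), namely a flox control, cre control 2 or 3, flox MCD 2, cre MCD 1 or 2 or the library labelled cre MCD 3. Its 6 rises became 1 without cre control 1 or 2, 2 without cre MCD 2 and 3 without the library labelled cre MCD 3, and its 9 falls became 5 without cre control 2 or cre MCD 2. Of 27 bile acid genes 2 rose and 4 fell (3 and 6 over the list alone), Slco1a1 from 28.7 ± 19.5 to 0.213 ± 0.108 CPM. The bile acid set fell (adjusted p = 0.046, and adjusted p = 0.46 with an estimated correlation). Again 9 libraries each ended the call when left out (adjusted p of 0.053 to 0.15), namely a flox control, cre control 2 or 3, flox MCD 1 or 2 and cre MCD 1 or 2. Pancreas and red cell markers rose as a set (adjusted p = 0.046, and adjusted p = 0.47 with an estimated correlation), with 1 of 8 risen and 4 over the list alone. That call was lost without flox control 1 or 2, cre control 1 or 3, flox MCD 1, cre MCD 2 or the library labelled cre MCD 3 (adjusted p of 0.05 to 0.19).

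The remaining lists did not change as sets in cre mice. Of 16 sulfotransferases 2 rose and 5 fell (4 and 5 over the list alone), with Sult2a3, of the steroid and bile acid sulfotransferases, at 4.06 and Sult2a8 at -3.51. Their set had an adjusted p of 0.33, a median of 0.25 and a mean of -0.73, and without cre MCD 2 the 5 falls became 3. Of 24 cytochromes P450 4 rose and 2 fell (5 and 2 over the list alone, set adjusted p = 0.78), with Cyp2c55 at 2.41 and Cyp2c40 at -1.51. Of 25 acute phase genes 1 rose and 2 fell (3 and 3 over the list alone, set adjusted p = 0.78), Apcs from 140 ± 35.6 to 908 ± 48.5 CPM. Of 24 immediate-early genes 3 rose and 1 fell (5 and 2 over the list alone, set adjusted p = 0.27), with Atf3 at 1.84 and the phosphatase Dusp1 at -1.65. Hepatocyte (adjusted p = 0.096), lymphocyte (adjusted p = 0.063), circadian (adjusted p = 0.066) and chemokine lists (adjusted p = 0.73) each held 0 risen and 2 fallen genes. Endothelial (adjusted p = 0.19) and adipocyte and gallbladder lists (adjusted p = 0.47, median -0.02, mean 0.10) each held 1 risen gene. Resident macrophage (adjusted p = 0.78) and neutrophil lists (adjusted p = 0.74) held 0. The total of 1118 became 1893 without flox control 3, 466 without cre control 1, 427 without cre control 2, 633 without cre control 3, 1929 without cre MCD 1, 319 without cre MCD 2 and 545 without the library labelled cre MCD 3. DESeq2 called 2229, of which 1098 were shared, and on FPKM the median of all genes moved by 0.276 and the calls were 946 higher and 215 lower.

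**Figure D3:**
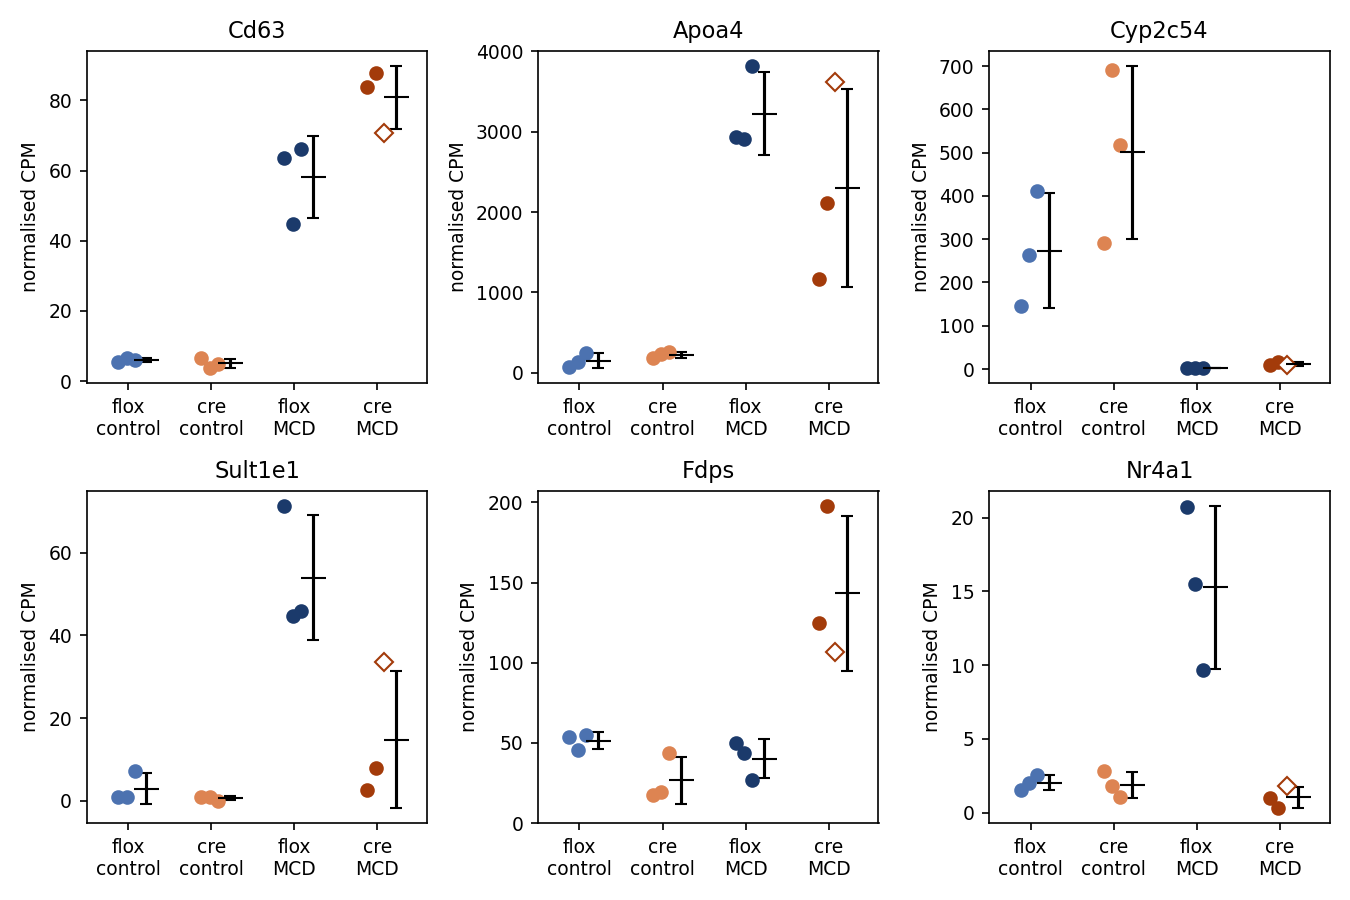
Normalised CPM of Cd63, Apoa4, Cyp2c54, Sult1e1, Fdps and Nr4a1 in each library by group; bars are means with the SD of 3 libraries, and the open diamond is the library labelled cre MCD 3. Cd63 and Apoa4 are higher and Cyp2c54 lower on MCD in both genotypes, and the highest Fdps values are in cre MCD.

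The third comparison asks how cre and flox livers differed on the MCD diet, the setting in which the series studies Lpcat3. Among cre MCD libraries, with the library labelled cre MCD 3 included, the immediate-early gene Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), an orphan nuclear receptor, was lower at 1.04 ± 0.72 against 15.3 ± 5.54 CPM (log2 fold change -3.87, SE 0.53, adjusted p = 0.04). Endod1 (ENSMUSG00000037419, chromosome 9, 14353990 to 14381507), an endonuclease-domain gene, was lower at 3.37 ± 0.856 against 12.3 ± 1.2 CPM (-1.86, SE 0.25, adjusted p = 0.04). The Nr4a1 call was lost without flox control 1 or 2, cre control 2, flox MCD 1 or 2, or cre MCD 1 or 2 (adjusted p of up to 0.11), and the Endod1 call also without flox MCD 3 (up to 0.194). No other gene passed in edgeR with all 12 libraries, TMM scaling and the filter by counts, while the other edgeR fits called 0 to 46. As a set immediate-early genes were lower in cre livers (adjusted p = 1.2e-23, and adjusted p = 0.012 with an estimated correlation). The set calls of cholesterol synthesis (higher) and of matrix and recruited macrophage genes (lower) were lost with the other test (adjusted p = 0.11, 0.13 and 0.14 with an estimated correlation). At an unadjusted p under 0.05 there were 1376 genes; DESeq2 called 189 and limma voom 12, both with these 2 genes among them.

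Cholesterol synthesis had all 25 members above 0 in cre against flox livers, with a median of 1.12. Over all genes 0 passed, and 20 did adjusted over the list alone (set adjusted p = 9.6e-33, and adjusted p = 0.11 with an estimated correlation). Dhcr7, the last reductase of the pathway, stood at 33.9 ± 9.2 against 11.7 ± 2.35 CPM (1.54, adjusted p = 0.05, just short of passing) and Fdps at 1.83 (adjusted p = 0.12). Immediate-early genes were lower as a set (adjusted p = 1.2e-23, and adjusted p = 0.012 with an estimated correlation). Of its 24 members 1 was lower over all genes and 13 over the list alone, with Jun at -1.70 (adjusted p = 0.05) and Atf3 at -1.83 (adjusted p = 0.096). In the 8 lists that follow, 0 members passed over all genes and the counts are those over the list alone. Extracellular matrix genes were lower, with 12 of 34 lower (set adjusted p = 8.2e-14, and adjusted p = 0.13 with an estimated correlation). Recruited macrophage markers were lower, with 10 of 22 lower (set adjusted p = 3.2e-10, and adjusted p = 0.14 with an estimated correlation) and Gpnmb at -3.83 (adjusted p = 0.096). Chemokines and cytokines were lower, with 1 of 23 higher and 4 lower (set adjusted p = 2.7e-06, and adjusted p = 0.13 with an estimated correlation). PPARalpha targets were lower, with 1 of 26 lower (set adjusted p = 1.5e-05, and adjusted p = 0.35 with an estimated correlation). Lymphocyte markers were lower, with 0 of 25 past the threshold (set adjusted p = 0.00071, and adjusted p = 0.19 with an estimated correlation). Cytochromes P450 were higher, with 3 of 24 higher (set adjusted p = 1.5e-07, and adjusted p = 0.13 with an estimated correlation). Sulfotransferases were higher, with 3 of 16 higher and 1 lower (set adjusted p = 2.6e-05, and adjusted p = 0.13 with an estimated correlation). Fatty acid synthesis was higher, with 3 of 28 higher (set adjusted p = 9.1e-05, and adjusted p = 0.13 with an estimated correlation). These 10 lists kept their calls with each library left out in turn.

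Another 10 lists passed as sets, with 0 members past the threshold over all genes, but lost the call when a library was left out. The values without that library are adjusted p as well. Higher in cre were methionine and one-carbon genes (adjusted p = 0.002, and adjusted p = 0.42 with an estimated correlation), at 0.17 without the library labelled cre MCD 3. So were hepatocyte markers (adjusted p = 0.0055, and adjusted p = 0.59 with an estimated correlation), at 0.82 without the same library. Endothelial markers were higher (adjusted p = 0.0055, and adjusted p = 0.35 with an estimated correlation), at 0.082 without flox MCD 3. Male-biased genes were higher (adjusted p = 0.023, and adjusted p = 0.49 with an estimated correlation), at 0.075 to 0.17 without flox MCD 2 or the library labelled cre MCD 3. Pancreas and red cell markers were higher (adjusted p = 0.023, and adjusted p = 0.41 with an estimated correlation), at 0.082 to 0.27 without flox MCD 3, cre MCD 2 or the library labelled cre MCD 3. Interferon genes were lower in cre (adjusted p = 0.00023, and adjusted p = 0.35 with an estimated correlation), at 0.082 without flox MCD 3. Neutrophil markers were lower (adjusted p = 0.0037, and adjusted p = 0.15 with an estimated correlation), at 0.076 without cre MCD 1. Resident macrophage markers were lower (adjusted p = 0.012, and adjusted p = 0.48 with an estimated correlation), at 0.093 to 0.32 without flox MCD 3 or cre MCD 1. Stellate cell markers were lower (adjusted p = 0.02, and adjusted p = 0.35 with an estimated correlation), at 0.054 to 0.28 without flox MCD 1 or cre MCD 1. Proliferation genes were lower (adjusted p = 0.022, and adjusted p = 0.56 with an estimated correlation), at 0.076 to 0.62 without flox MCD 3, cre MCD 1 or cre MCD 2. The other 14 lists had adjusted p of 0.055 to 0.96, with fatty acid oxidation at 0.075, triglyceride and lipid droplet genes at 0.055, phospholipid genes at 0.6 and bile acid genes at 0.056. In 3 of them the test direction, median and mean differed in sign, namely female-biased (adjusted p = 0.72, median -0.09, mean -0.08, direction higher), acute phase (adjusted p = 0.72, median 0.10, mean -0.19) and glycolysis genes (adjusted p = 0.65, median 0.04, mean -0.03).

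The count of 2 called genes became 0 without flox control 1, flox control 2, cre control 2, flox MCD 1 or cre MCD 2, 1 without cre MCD 1 and 10 without flox control 3. Without the library labelled cre MCD 3 there were 3 calls. Without it and flox control 3, chosen after the data were seen, there were 46 (16 higher and 30 lower), with Dhcr7 at 1.68, Cyp2c54 at 2.32, Gpnmb at -4.70 and Mmp12 at -3.96 among them. On FPKM the median of all genes moved by -0.110 and 30 genes passed, 1 higher and 29 lower.

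The fourth comparison asks how cre and flox livers differed on the control diet. Cre livers were higher in 3 genes and lower in 4 at this threshold, and 2 loci accounted for 4 of the 7. At Pakap (chromosome 4), a locus with overlapping gene models of A-kinase anchor and paralemmin proteins, the model ENSMUSG00000038729 (57717657 to 57896984) held 5.52 ± 0.384 CPM in cre and 0.101 ± 0.0435 in flox (log2 fold change 5.79, SE 0.32, adjusted p = 1.1e-06). The model ENSMUSG00000089945 (57568179 to 57896982) held 0 counts in cre and 6.04 ± 0.436 CPM in flox, at least 234-fold lower in cre against 3 counts over the group, and since the models overlap, the row to which a read was given is uncertain. The call of this model was lost without flox control 2 (adjusted p = 0.057). Gpc1, the proteoglycan glypican 1 (ENSMUSG00000034220, chromosome 1, 92831645 to 92860779), was higher in cre at 12.5 ± 1.24 against 1.27 ± 0.266 CPM (3.30, SE 0.28, adjusted p = 0.00012).

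Beside Gpc1, its overlapping neighbour Ankmy1 (92859803 to 92902906) had no count in flox control and was at least 39.2-fold higher in cre, against 3 counts over the group. Tlcd2, a membrane lipid protein, was lower in cre at 10 ± 1.75 against 48.3 ± 19.6 CPM, and Pdk4 at 11.3 ± 2.64 against 61.3 ± 16.5 CPM. The transcription factor Maff was lower as well (-2.47, adjusted p = 0.04), a gene outside the rule for named genes that is given after its value was seen. The Ankmy1 call was lost in 11 of the 12 fits, all but the one without the library labelled cre MCD 3 (adjusted p of up to 0.117). That of Pdk4 was lost without any library of the control groups or of flox MCD (up to 0.308), and that of Tlcd2 without flox control 2 or 3, any cre control or flox MCD 1 (up to 0.141). The Maff call was kept without cre control 3 or cre MCD 1 and lost in the other 10 fits (-2.64 to -2.20, adjusted p of up to 0.308). The 15 mitochondrially encoded genes were higher in cre as a set (adjusted p = 1e-16, and adjusted p = 0.19 with an estimated correlation), 0 of them over all genes and 12 over the list alone. Their member mt-Atp8 stood at 2.02 (adjusted p = 0.41). Beside this, mitochondrial coding genes held 23.4% ± 7.74 of all counts in cre control and 10.3% ± 4.24 in flox control. Cholesterol synthesis had all 25 members below 0 with a median of -0.50, and 0 passed over all genes and 2 over the list alone (set adjusted p = 8.3e-11, and adjusted p = 0.41 with an estimated correlation). Another 4 lists were lower as sets with 0 members past the threshold either way. Fatty acid synthesis had adjusted p = 2.3e-05, and adjusted p = 0.16 with an estimated correlation. Female-biased genes had adjusted p = 1.3e-05, and adjusted p = 0.16 with an estimated correlation. Interferon genes had adjusted p = 2.3e-07, and adjusted p = 0.41 with an estimated correlation. The unfolded protein response had adjusted p = 3.8e-05, and adjusted p = 0.63 with an estimated correlation. These 6 lists kept their calls with each library left out.

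Another 11 lists were lower as sets in cre control livers, but lost the call when 1 library was left out. Pdk4, in the PPARalpha and glycolysis lists, was the 1 member of these past the threshold over all genes. Without flox control 3, adjusted p went from 0.0011 to 0.72 for fatty acid oxidation, from 0.00021 to 0.13 for cytochromes P450, from 0.0021 to 0.28 for NRF2 and glutathione genes and from 0.0015 to 0.16 for glycolysis. These 4 lists had adjusted p = 0.66, 0.41, 0.63 and 0.53 with an estimated correlation. PPARalpha targets (adjusted p = 0.0011) and triglyceride genes (0.014) lost it without flox control 3 or cre control 2, at 0.058 to 0.57 and 0.086 to 0.91. Both had adjusted p = 0.63 with an estimated correlation. Hepatocyte markers (adjusted p = 0.032) and acute phase genes (0.029) lost it without flox control 3 or cre control 1, at 0.3 to 0.72 and 0.3 to 0.77. The pair had adjusted p = 0.66 with an estimated correlation. Extracellular matrix genes (adjusted p = 0.0025) lost it without flox control 2 or cre control 2, at 0.05 to 0.21. Proliferation genes (0.004) lost it without cre control 2, at 0.056, and immediate-early genes (0.031) without flox control 3, cre control 2 or cre control 3, at 0.093 to 0.39. All 3 of these had adjusted p = 0.63 with an estimated correlation. The other 17 lists did not pass, the male-biased list at an adjusted p of 0.89 with a median of -0.02 and a mean of 0.00287.

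At an unadjusted p under 0.05 there were 1190 genes, and DESeq2 called 59 and limma voom 5. The count of 7 became 2 without flox control 2 and 4 without flox control 3, flox MCD 1 or flox MCD 3, while on FPKM 2 genes passed, 1 in each direction.

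The fifth comparison asks whether the diet effect differed between the genotypes, again with the library labelled cre MCD 3 in the cre MCD group. The 25 cholesterol synthesis genes had a median log2 fold change for the diet of -0.44 in flox livers (0.0938 on FPKM values, and -0.32 there relative to the median of all genes) and 1.13 in cre livers. Their differences had a median of 1.73, with 0 of 25 past the threshold over all genes (set adjusted p = 1.2e-37, and adjusted p = 0.072 with an estimated correlation). Only 1 gene passed over all genes, the Pakap model ENSMUSG00000038729 (difference of log2 fold changes -6.45, SE 0.40, adjusted p = 4.1e-06), which in flox livers went from 0.101 ± 0.0435 to 12.7 ± 0.944 CPM. The Pakap models summed went only from 6.29 ± 0.609 to 12.7 ± 0.944 CPM there. The next smallest p values belonged to Gpc1 (-2.33, adjusted p = 0.15), Tlcd2 (2.58), Fdps (2.78) and Mt1 (-2.41, each adjusted p = 0.21). At an unadjusted p under 0.05 there were 1483 genes; DESeq2 called 99 and limma voom 0.

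Cholesterol synthesis passed with 21 of 25 genes higher over the list alone (set adjusted p = 1.2e-37, and adjusted p = 0.072 with an estimated correlation). In this and the next 8 lists 0 members passed over all genes and the counts are those over the list alone. Fatty acid synthesis was higher, with 4 of 28 (set adjusted p = 1.6e-08, and adjusted p = 0.072 with an estimated correlation). Cytochromes P450 were higher, with 3 of 24 (set adjusted p = 3.5e-10, and adjusted p = 0.12 with an estimated correlation). Sulfotransferases were higher, with 3 of 16 up and 1 down (set adjusted p = 0.00019, and adjusted p = 0.19 with an estimated correlation). Female-biased genes were higher, with 4 of 29 (set adjusted p = 0.0017, and adjusted p = 0.19 with an estimated correlation), as was the unfolded protein response, with 0 of 29 (set adjusted p = 0.00019, and adjusted p = 0.48 with an estimated correlation). For mitochondrially encoded genes the diet effect in cre livers lay below that in flox livers, with 9 of 15 lower (set adjusted p = 4.9e-12, and adjusted p = 0.19 with an estimated correlation). The same held for immediate-early genes, with 3 of 24 lower (set adjusted p = 3.3e-07, and adjusted p = 0.12 with an estimated correlation). Neutrophil markers were lower too, with 2 of 7 (set adjusted p = 0.0041, and adjusted p = 0.19 with an estimated correlation). These 9 lists kept their calls with each library left out, and a further 8 did not. Methionine and one-carbon genes (adjusted p = 0.0016) and NRF2 and glutathione genes (0.0019) were higher, calls lost without flox control 3 (0.075 and 0.053). Hepatocyte markers (0.00095) were higher, a call lost without flox control 3 or the library labelled cre MCD 3 (0.079 to 0.11). These had adjusted p = 0.48, 0.48 and 0.57 with an estimated correlation. Glycolysis was higher (adjusted p = 0.013), a call lost without flox control 3, cre control 2 or the library labelled cre MCD 3 (0.068 to 0.11). Pancreas and red cell markers were higher (0.021), a call lost without flox control 2 or 3, cre control 1, flox MCD 3 or the library labelled cre MCD 3 (0.055 to 0.15). Both had adjusted p = 0.48 with an estimated correlation. Recruited macrophage markers were lower (adjusted p = 0.0029), a call lost without flox MCD 1 or cre MCD 1 (0.067 to 0.072). Matrix genes were lower (0.0086), a call lost without flox control 3, cre control 1, flox MCD 1 or flox MCD 3 (0.057 to 0.13). Chemokines were lower (0.031), a call lost without flox control 1, cre control 1, flox MCD 1 or 3, or cre MCD 1 (0.057 to 0.21). These 3 lists had adjusted p = 0.48, 0.57 and 0.48 with an estimated correlation. The other 17 lists did not pass, and the signs of median and mean differed for triglyceride (0.02 and -0.01), phospholipid (0.18 and -0.07) and proliferation genes (-0.23 and 0.07).

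**Figure D4:**
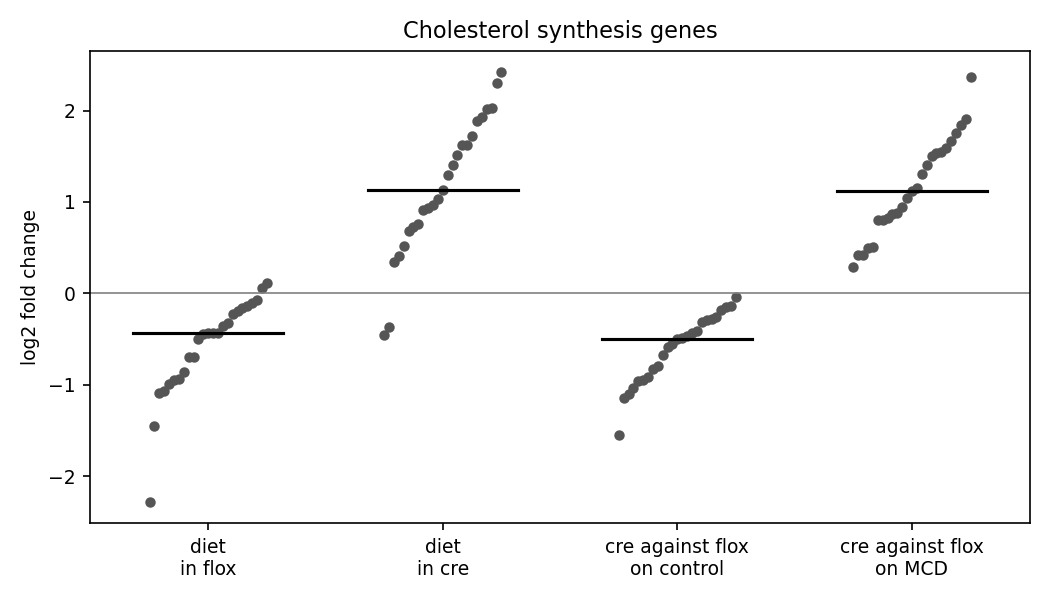
Log2 fold change of each of the 25 cholesterol synthesis genes for the MCD diet in flox and in cre mice and for cre against flox on each diet; points are genes and the line is the median. All 25 points lie above 0 for cre against flox on MCD and below 0 on the control diet; on FPKM values the median for the diet in flox mice turns from below to above 0, but all genes shift with it, and relative to their median it stays at -0.32.

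With 7 and 2 calls, too few for an overlap to be looked for, the effects of genotype on the 2 diets were compared across all genes, and their log2 fold changes had a Pearson's r of -0.0327. In the interaction the count of 1 became 2 without flox control 3, any cre control, flox MCD 1, flox MCD 2 or cre MCD 1, with the Pakap model among them each time. Without the library labelled cre MCD 3 and flox control 3 there were 8, including Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis (-2.65, adjusted p = 0.00107), Tfpi2 (-3.29), Mt1 (-2.90) and Elovl6 (2.22); these were named after their values were seen. On FPKM the median of all genes moved by -0.122 and 1 gene passed, which was not the Pakap model.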

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

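The placement of the library labelled cre MCD 3 between the genotypes was planned before its value was seen, whereas the condition that it must also separate the control libraries, and the tests of a swap, a mixture, gene models, ribosomal share and substrain, were chosen only after the result was seen.

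The transcript table, which no comparison between groups uses, held the full-length Lpcat3 transcript at 23.2 FPKM in the library labelled cre MCD 3 and at 0 in the other 5 cre libraries. A swap with a library labelled flox is argued against by 0 flox libraries without that transcript. The retained-intron transcript was at 0 FPKM in this library and at 3.54 to 5.39 FPKM in the other cre libraries. This cannot decide on cre and flox RNA mixed in similar amounts. In no library did both transcripts exceed 0.265 FPKM, so the counts of a mixture may all have gone to the full-length one. The whole gene, whose counts sum all transcripts, stood at 56.1 CPM in this library. It was at 41.4 to 63.4 CPM in flox and 16.1 to 23.3 CPM in the other cre libraries. RNA mixed in similar amounts would lie about midway between these ranges, so this level argues against such a mixture. Over the genes that best separate the other 5 MCD libraries, the library labelled cre MCD 3 lay at 0.608 between cre (0) and flox (1). The flox MCD libraries lay at 0.513 to 0.78 and cre MCD 1 and 2 at 0.299 to 0.557. The position of 0.608 met the condition set beforehand for a wrong genotype label or an animal without the deletion. Genes chosen anew in the same way from the control libraries did not place flox control (0.158 to 0.512) apart from cre control (0.308 to 0.587). Such a placement may therefore not measure genotype. A wrong label, an animal without the deletion, a mixture made mostly of flox RNA or a swap with a liver from elsewhere stay open. No biological explanation was tested, since the labels give none.

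The diet effect on Pakap (ENSMUSG00000038729) differed between the genotypes by -6.45 on the log2 scale (adjusted p = 4.1e-06), and flox control lay apart from the other 9 libraries there and at Gpc1. The ribosomal share of the libraries is argued against for Gpc1. Its log2 fold change for cre against flox on the control diet was 3.31 with that share as a covariate and 3.30 without. A C57BL/6J against C57BL/6N difference is argued against by Nnt with its 2 rows summed. The sum stood at 58.4 ± 10.6 CPM (n = 3) against 60.1 ± 20.3 CPM (n = 9), a ratio of 0.972. The second row held 85.3 CPM in flox MCD 3, 33.3 in flox MCD 2, 13.1 in cre MCD 2 and 0 in the other libraries. The first row held 2.29 CPM in flox MCD 3, so the row to which Nnt counts went is uncertain. For Pakap a candidate explanation is that counts went to another of its overlapping gene models, since the summed models stood at 6.29 ± 0.609 CPM in flox control and 5.52 ± 0.384 CPM in cre control, a ratio of 1.14. Of the 220 trios of libraries 4, flox control among them, were set apart from the other 9 at 4 or more genes, here Gpc1, Cyp2c70 and 2 Pakap models, and the highest, flox MCD, at 7. Other parents or another sequence at these loci in the flox control mice, and an effect of diet and genotype together, stay open as untested.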

How the results depend on the processing

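Of the alternatives in this part, leaving out the library labelled cre MCD 3 together with flox control 3, removing the ribosomal rows and the ribosomal share as a covariate were tests chosen only after the results were seen.

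Over all alternatives, 377 values that answer a comparison kept their direction and their side of the threshold or stayed within 1.5 times, 74 counts moved further, 20 values reversed, 12 lost the threshold and 1 gained it. For the lists 1475 values stayed, 285 lost the threshold and 7 reversed, and for the named genes 4882 stayed, 619 lost the threshold and 0 reversed. With each library left out in turn, 18 of 20, 10 of 19, 10 of 20, 6 of 17 and 9 of 17 list calls were kept in all 12 fits (diet in flox, diet in cre, genotype on MCD, genotype on control, interaction), as were 71 of 102, 56 of 104, 0 of 2, 2 of 6 and 1 of 1 calls of named genes. Those fits rest on fewer samples by construction, and why single libraries raised counts was not tested. An analysis of genes with a symbol only was not run, since all genes have a name and it moves nothing.

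The 871 genes for the diet in flox mice became 1653 with DESeq2, 1815 with log2(FPKM + 1), 1708 with log2(FPKM + 0.1), 1821 with log2(FPKM + 1) and no filter, 1401 without the 2 doubted libraries, 1439 with the ribosomal share as a covariate and 425 to 1055 with 1 library left out. For the diet in cre mice, 1118 became 2229 with DESeq2, 2005 with the replicate block, 389 with log2(FPKM + 1) and no filter, 1835 with the covariate and 319 to 1929 with 1 library left out. Of 18 same-numbered pairs 2 had an r over 0.1, but 8 of 12 libraries had their best match in another group at their own number, so pairing by number is not excluded.

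For genotype on MCD, 2 genes became 5 with DESeq2's size factors, 20 with no filter, 5 with a CPM of at least 1, 189 with DESeq2, 12 with limma voom and 6 with the replicate block. They became 30 with log2(FPKM + 1), 1 with log2(FPKM + 0.1), 31 with log2(FPKM + 1) and no filter, 0 with only the 6 libraries compared, 46 without the 2 doubted libraries, 4 without ribosomal rows, 22 with the covariate and 0 to 10 with 1 library left out. With only the 6 libraries compared, 1693 genes had an unadjusted p under 0.05 in edgeR. For genotype on the control diet, 7 became 59 with DESeq2, 2 with log2(FPKM + 1), 1 with log2(FPKM + 0.1), 2 with log2(FPKM + 1) and no filter and 2 to 7 with 1 library left out. In the interaction, 1 became 8 with no filter, 99 with DESeq2, 0 with limma voom, 0 with log2(FPKM + 0.1), 2 with log2(FPKM + 1) and no filter, 8 without the 2 doubted libraries, 3 with the covariate and 1 to 2 with 1 library left out. The cause of these moves was not tested.

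The rise of Sult1e1 kept its direction in both genotypes under each alternative. In flox mice it ranged from 3.73 to 6.02 with 1 library left out. In cre mice it missed the threshold at 5.50 with limma voom and 2.62 with log2(FPKM + 1) and no filter, and ranged from 3.19 to 5.16 with 1 library left out. Its interaction, 0.48 and far from the threshold, reversed to -0.864 with the replicate block, -1.66 with log2(FPKM + 1), -0.96 with log2(FPKM + 0.1), -1.66 without the FPKM filter, -2.83 without the 2 doubted libraries, -0.882 with the covariate, and ranged from -1.37 to 0.984 with 1 library left out. The cause was not tested.

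For Lpcat3 the diet effect in flox mice, -0.03 and far from the threshold, reversed to 0.0027 with no filter, 0.453 with log2(FPKM + 1), 0.475 with log2(FPKM + 0.1), 0.453 without the FPKM filter and 0.141 without the 2 doubted libraries, and ranged from -0.114 to 0.141 with 1 library left out. On log2(FPKM + 1) and log2(FPKM + 0.1) values with the filter the median of all genes moved alike, by 0.415 and 0.525. Relative to it Lpcat3 lay at 0.0384 and -0.05, so most of these 2 moves is the shift of all genes. Without the FPKM filter the median moved by only 0.0703, and Lpcat3 lay at 0.383 relative to it. The diet effect in cre mice, 0.57, reversed to -0.131 without the 2 doubted libraries and ranged from -0.131 to 0.889 with 1 left out, and the interaction, 0.60, reversed to -0.272 and ranged from -0.106 to 0.914. Cre against flox on MCD passed at -1.40 without the 2 doubted libraries (adjusted p = 0.0322, and 0.0701 to 1 under all other alternatives). Since the library labelled cre MCD 3 holds flox-like Lpcat3 (56.1 CPM), its removal by construction moved the values that involve the cre MCD group, and the cause of the other reversals was not tested.

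With an estimated correlation the called lists went from 20, 19, 20, 17 and 17 to 1, 0, 1, 0 and 0 in the order of comparisons above. With fry they went to 17 and 9 for the diet in flox and in cre mice, 1 and 0 for genotype on MCD and on control and 3 for the interaction. For genotype on control 9 lists were called without the 2 doubted libraries and 9 to 19 with 1 library left out. There the median of fatty acid oxidation, -0.25, reversed to 0.047 without the 2 doubted libraries and ranged from -0.501 to 0.0474 with 1 left out, and that of triglyceride genes, -0.31, reversed to 0.0103 and ranged from -0.397 to 0.0108. The hepatocyte list turned to a test direction of higher at a median of -0.025 without the 2 libraries, ranged from -0.373 to -0.0246 with 1 left out, and in the interaction turned to lower at a median of 0.0862. The highest of these medians were those without flox control 3. That library and the library labelled cre MCD 3 had the lowest ribosomal shares (7.34% and 5.6%) and an r of 0.345 with each other, and why these lists moved was not tested.

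With the estimated counts taken as reads, depth limits genes at 0 to a floor of 3 counts over a group, or 0.0144 to 0.0258 CPM. On simulated data 2% to 12% of 2-fold changes were called, so most changes of that size were missed there. Those data held 100 genes changed 2-fold and 100 changed 4-fold per comparison. The share does not carry over to the diet comparisons, where 871 and 1118 calls make the adjusted threshold less strict.

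The 6 libraries of each of 4 comparisons have 10 splits, too few for a share under 0.05. With the real split against the highest of the others, the diet gave 871 against 1 gene in flox and 1118 against 0 in cre mice, so that 1 of 10 splits, the real one, gave as many in each. Genotype on the control diet gave 7 against 1, again 1 of 10. Genotype on MCD gave 2 against 2, in 2 of 10 splits, the other one with flox MCD 2 and the library labelled cre MCD 3 exchanged. For the interaction 15 of 100 drawn splits gave at least the 1 gene of the real labels, and the highest other gave 5, so chance is not excluded for that count.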

Other observations

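The tests of the sex of the libraries in this part were chosen only after the result was seen.

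All 12 libraries carry a male label, yet Xist stood at 116 to 685 CPM and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d at 0 of 594762605 counts, which allows up to 0.005 CPM for each. Male livers whose Y-linked counts were lost are argued against by the lowest Xist level of 116 CPM. Xist at this level with no Y-linked count, in each of the 12 libraries, argues against the male label. Female livers remain the candidate explanation. That 12 of 12 libraries had Xist over 10 CPM and no Y-linked count restates the observation and is not a separate test of it. What stays open is whether the labels or the animals differ from the study plan, and no biological explanation was tested.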
